A study of Homo sapiens with 3 samples.

How the data were processed

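Gene expression was measured in MCF-7 cells, an established human breast cancer line, on 3 Affymetrix Human Genome U133 Plus 2.0 arrays. Each array held 1 condition: control medium, 250 µM desferrioxamine (DFO) for 24 h, or 25 µM of the chelator named 311 for 24 h. Groups were taken from the sample labels, which give 1 sample per condition.

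The deposited values are intensity signals on a linear scale, 1 per probe set and array, made with GCOS 1.3 per the submitters' processing notes. GCOS is the manufacturer's software that turns the scanned probe cells of an array into 1 signal per probe set. Its background and scaling settings are not given in the sources used here. On each array the mean signal without the lowest and highest 2% of probe sets was 150.02, so the arrays had been scaled to a common target before deposit. Such scaling sets the average of the bulk of probe sets equal, and a shift shared by most transcripts cannot be read from it. The table used here held no detection calls. RNA was extracted with TRIzol and labelled by the manufacturer's standard protocol, per the labels' protocols.

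Each array had 54675 probe sets, of which 62 were the manufacturer's control probe sets. Probe sets were named through the platform's gene table: 41091 had 1 gene, 1801 had several and 11721 had none, and a probe set of the last group is unnamed here. Names were looked up by gene number in a current RefSeq gene table, where 41037 probe sets matched and 0 names differed. This gave 19775 genes. FTH1 and TP53, which had been chosen for reporting before the data were examined, were not named by the table and were not analysed here. No genomic coordinates are given, because no genome build is named in the sources used here.

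A signal under an array's 50th percentile of all probe sets was set to that percentile, called the floor, which was 36.97 on the control array, 45.11 on the DFO array and 47.45 on the 311 array. A gene was represented by its brightest probe set, by mean log2 signal over the 3 arrays. The log2 ratio of each pair of arrays was computed for genes above the floor on at least 1 array of the pair, called measured genes. Where 1 side lay under the floor, a fold of 2 or more is a lower bound and is written as "at least". Each array was set to its own floor, and the floors differ. A gene just above the control floor and under a chelator floor could therefore enter as slightly higher with the chelator although its signal was lower. CD3E, at 38.3 on the control array and 23.1 on the DFO array, entered the DFO comparison in this way. A gene was counted as higher or lower when its ratio reached 2-fold. This is a rule of size, not a test: with 1 array per condition, no p-value was computed.

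In place of a replicate error, the disagreement between probe sets of the same gene was used. The SD of the log2 ratio of 1 probe set was estimated from 4436 genes with 2 probe sets above the floor, by dividing the SD of their difference by the square root of 2. It holds differences between transcript isoforms as well as technical error, and no error between cultures. The noise of each array was derived from the 3 pairwise values and was 0.432 on the control array, 0.239 on the DFO array and 0.328 on the 311 array, as the SD of a log2 signal. With this noise, 100 sets of 3 arrays with no differences between conditions were simulated. They gave the counts, overlaps and correlations that this noise and the shared control array produce. The simulated arrays had 1 common floor, the mean of the 3 log2 floors. Dimmer genes were given the noise of the dimmest probe sets above the floor on all 3 arrays. The simulated counts therefore leave out the unequal floors and any further noise of genes under the floor.

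A total of 26 gene lists with 623 genes were fixed before the data were examined. They covered iron uptake, storage and export; heme synthesis and iron-sulfur cluster assembly; hypoxia-inducible factor targets; glycolysis; p53 targets; mitosis; DNA replication; estrogen receptor targets and luminal genes; the ATF4 response; the unfolded protein response; oxidative phosphorylation; cholesterol synthesis; NRF2 targets; metallothioneins and zinc transport; iron- and oxoglutarate-dependent dioxygenases; the BCL2 family; autophagy; immediate early genes; NF-kB targets; interferon-stimulated genes; histones; reference genes; and markers of fibroblasts, leukocytes, basal epithelium, and liver or neurons. For each list the median log2 ratio of its measured members was set among 10000 random lists of the same size, drawn with replacement and matched on mean log2 signal in 20 bins. The percentile describes these arrays and is not a test of the conditions. A list median below percentile 2.5 or above 97.5 is called outside the random range. A range beside a list's median gives its lowest and highest value over the alternatives of scaling, floor and probe set, the value as deposited included, and this range or the value under a named alternative is printed where the median turned sign or moved by more than 1.5 times.

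Genes were named by a rule fixed before the data were examined. It took TFRC, NDRG1, VEGFA, CDKN1A, FTH1, CCND1 and TP53; the 10 highest and the 10 lowest log2 ratios among genes above the floor on both arrays whose other measured probe sets had the same sign; up to 4 members of each list with the largest absolute log2 ratio; and up to 3 genes per direction with a lower bound. Any gene outside the rule is said to have been chosen after its values were seen.

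The procedure was tested on simulated data for DFO against control, with 13194 genes. The 2-fold rule called 99.0% of genes simulated with a log2 change of 2, 100% of those with a change of 3, and 4.02% of unchanged genes. A list of 30 raised genes reached percentile 100, and 93.0% of 100 lists of unchanged genes stayed within the random range.

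Alternatives covered the scaling (median, quantile and intensity-dependent loess centring with a span of 0.3), the floor (the 40th or 60th percentile, or none with log2 of the signal plus 1), the probe set (the mean over a gene's probe sets, or the brightest after leaving out names ending in _x_at or _s_at) and the size rule (1.5-fold or 3-fold). Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.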

Results

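MCF-7 cells, a human breast cancer line that expresses the estrogen receptor, were profiled on 3 oligonucleotide arrays: 1 from control medium, 1 from cells given 250 µM DFO for 24 h, and 1 from cells given 25 µM 311 for 24 h. DFO (desferrioxamine) is an iron chelator in clinical use for iron overload. The compound 311 is named in the labels as 2-hydroxy-1-napthylaldehyde isonicotinoyl hydrazone, also an iron chelator. The series' design text explains the concentrations: both raise iron-responsive genes such as the transferrin receptor, and DFO was given at the higher dose because it crosses membranes poorly. There were no replicates, so every ratio compares 2 single arrays and no difference was tested. The number of arrays limits the precision. As a stand-in for technical error, the log2 ratio of 1 probe set had an SD of 0.49 for DFO against control, 0.54 for 311 against control and 0.41 for 311 against DFO, estimated from 4436 genes with 2 probe sets.

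Of 19775 named genes, 11998 lay above the floor on the control array, 12550 on the DFO array and 12758 on the 311 array. The control array stood apart in its control probe sets. The poly-A spikes, bacterial transcripts added to the RNA before labelling, had a median signal of 1296.9 on the control array, 146.5 on the DFO array and 153.4 on the 311 array. All 24 of their probe sets were lower on each chelator array than on the control array. The 18S ribosomal RNA probe sets had median signals of 319.3, 64.0 and 82.7 in the same order, whereas those of the hybridization spikes, added after labelling, were 617.6, 752.3 and 709.3. The signal ratio of the 3' to the 5' probe set, a measure of RNA integrity, was 1.23, 1.08 and 1.10 for ACTB and 1.01, 0.925 and 0.977 for GAPDH. Log2 signals correlated across genes at 0.953 between the chelator arrays, 0.882 between DFO and control, and 0.891 between 311 and control.

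**Figure D1:**
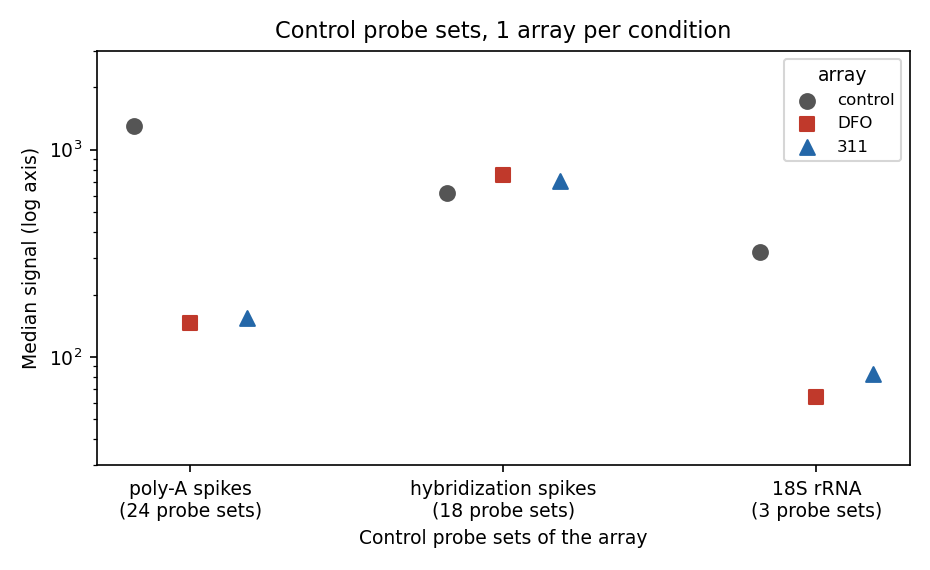
Median signal (log axis, linear intensity units) of the array's control probe sets, with 1 point per array: 24 poly-A spike probe sets, 18 hybridization spike probe sets and 3 probe sets for 18S ribosomal RNA. The control array is at 1296.9 for the poly-A spikes against 146.5 and 153.4 on the chelator arrays, while the hybridization spikes lie between 617.6 and 752.3 on all 3.

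The first comparison asked which transcripts differed between DFO-treated and control cells. After DFO, targets of the hypoxia-inducible factors, the transcription factors that respond to low oxygen and are marked for degradation by iron-dependent hydroxylases, were higher as a group. Of 37 measured targets, 33 were higher by the 2-fold rule, 0 were lower and 4 lay within 2-fold, with a median log2 ratio of 2.10 (percentile 100 among random lists). IGFBP3, which binds insulin-like growth factors, was 61.5-fold higher, BHLHE40, a transcriptional repressor, 12.2-fold, the vasodilator peptide gene ADM 11.99-fold and NDRG1, a metastasis suppressor, 11.4-fold (576 on the control array and 6549 on the DFO array). Genes of mitosis were lower as a group: 32 of 40 were lower by the rule and 0 were higher, with a median of -1.62 (percentile 0.0). The transferrin receptor gene TFRC, which brings iron into the cell, was 2.54-fold higher, and its 3 measured probe sets had log2 ratios of 1.25 to 1.56.

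Glycolysis genes shared the direction of the hypoxia targets. Of 21 measured, 15 were higher by the rule and 0 were lower (median 1.34, percentile 100), including the enolase ENO2 at 17.5-fold, the aldolase ALDOC at 8.79-fold and the glycogen branching enzyme GBE1 at 6.98-fold. The dioxygenases that use iron and oxoglutarate had a median of 0.42 (percentile 99.73, range -0.02 to 0.48), with 6 of 34 higher and 3 lower, and a median of -0.02 without the _x_at and _s_at probe sets. All 6 higher members also stand on the hypoxia list, among them EGLN3, a prolyl hydroxylase of the hypoxia-inducible factors, at 8.88-fold and the histone demethylase KDM3A at 6.55-fold. VEGFA, an angiogenic growth factor, had a log2 ratio of 0.59 on the brightest of its 4 measured probe sets. The others were past 2-fold, at log2 ratios of 1.45, 1.52 and 1.79.

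Iron handling genes were higher in 6 of 22 measured cases and lower in 0 (median 0.66, percentile 99.77). STEAP3, an endosomal ferrireductase, was 5.68-fold higher, the iron chaperone PCBP1 2.98-fold and the heme oxygenase HMOX1 2.60-fold. Heme synthesis and iron-sulfur cluster genes had a median of -0.52 (percentile 0.25, range -0.52 to -0.18). Of these 29 genes, 2 were higher, 4 were lower and 23 lay within 2-fold. ISCA1 was 3.58-fold higher and PPOX, an enzyme of heme synthesis, 2.16-fold higher, while the cochaperone HSCB was 2.59-fold lower and ISCA2 2.16-fold lower. Metallothionein and zinc transport genes had a median of 2.15 (percentile 100), with 7 of 12 higher and 1 lower. MT1X was 26.2-fold and MT2A 15.5-fold higher. The metallothioneins are near-identical paralogs read by probe sets marked _x_at, which share probes with related transcripts, so their separate values are uncertain, and without such probe sets the list's median was 0.18.

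Among cell cycle genes, the kinetochore gene NDC80 was 10.9-fold lower, the motility receptor HMMR 8.92-fold, cyclin B1 (CCNB1) 7.65-fold and the Aurora kinase gene AURKA 7.04-fold. Genes of the G1/S transition and DNA replication were lower in 12 of 42 cases and higher in 0 (median -0.61, percentile 0.01), with the polymerase subunit POLE2 6.25-fold lower. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 8.23-fold higher, at 455 on the control array and 3742 on the DFO array. It belongs to the p53 target list, of which 7 of 30 were higher and 0 lower (median 0.52, percentile 99.85, range 0.17 to 0.59), GADD45A among them at 4.78-fold. Cyclin D1 (CCND1) was within 2-fold, with a log2 ratio of -0.38.

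Immediate early genes had a median of 1.61, with 14 of 19 higher and 0 lower (percentile 100), such as MAFF at 8.16-fold and FOS at 7.91-fold. The ATF4 response had a median of 0.57, with 11 of 31 higher and 0 lower (percentile 99.96), led by the transcription factor ATF3 at 20.9-fold and PPP1R15A, a phosphatase subunit of the integrated stress response, at 8.87-fold. NF-kB targets had a median of 0.57, with 4 of 14 higher and 1 lower (percentile 98.23, range 0.27 to 1.10), including the chemokine gene CXCL8 at 14.4-fold and TNFAIP3, an inhibitor of NF-kB signalling, at 10.5-fold. Estrogen receptor targets and luminal genes were lower in 10 of 31 cases and higher in 2, and their median of -0.15 lay within the random range (percentile 7.05, range -0.43 to -0.09). XBP1 was 4.16-fold lower and GREB1 4.04-fold lower. The receptor gene ESR1 was 5.71-fold lower on its brightest probe set, but its 4 measured probe sets ran from -2.51 to 0.49. Basal epithelial markers had a median of 2.96 over 4 measured genes (1.71 without a floor), of which 3 were higher by the rule. TRIM29 was 20.7-fold higher, the integrin ITGB4 7.82-fold and the growth factor receptor EGFR 7.75-fold, whereas CDH3 lay within 2-fold at a log2 ratio of 0.47. The basal keratin KRT5 lay under the floor on all arrays.

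Genome-wide, 1669 of 13687 measured genes were higher and 1209 lower by the 2-fold rule on the DFO array, of which 510 and 129 had a lower bound only. Outside the lists, the highest ratios included the neuronal pentraxin NPTX1 at 55.7-fold and the connexin GJB2 at 20.97-fold, and the lowest included the extracellular matrix gene HMCN1, 16.1-fold lower, the polyamine synthesis enzyme ODC1, 11.3-fold lower, and the nuclear lamina gene LMNB1, 10.1-fold lower. LOX, a collagen crosslinking enzyme and hypoxia target, was at least 52.3-fold higher. These ratios are against the array on which the poly-A spikes were 7.769-fold and the 18S RNA 5.0-fold above the DFO array, as the median of the probe sets' ratios. The split between directions depended on the scaling, with 1309 higher and 1278 lower genes (50.6% higher) after loess centring and 1901 and 1030 (64.9% higher) with median scaling. It also moved with the floor: without one, 64.5% were higher, against 58.0% in the main setting. The floor was 36.97 on the control array and 45.11 on the DFO array. A gene under the floor on 1 array therefore passed the rule as higher at a smaller signal than as lower. How much of the split comes from these unequal floors was not tested. Simulated arrays with no differences gave 196.5 higher and 246.2 lower genes on average. The median of all genes was 0.12, and loess centring moved it by -0.11. Relative to the median of all genes, the hypoxia list stood at 1.98 and the mitosis list at -1.74.

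**Figure D2:**
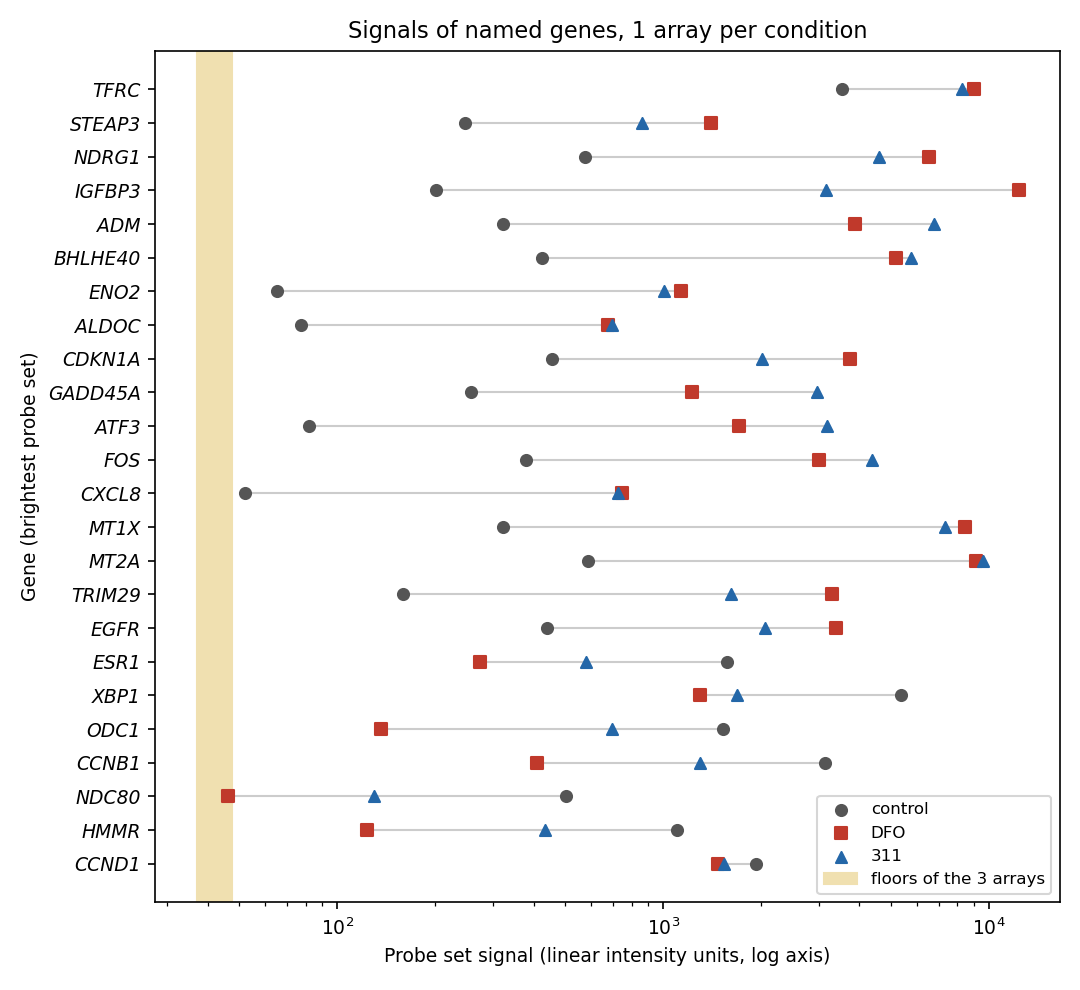
Signals of 24 named genes (horizontal log axis, linear intensity units) on the control, DFO and 311 arrays, with 1 point per array and no error bars because each condition had 1 array; the shaded band spans the floors of the 3 arrays. TFRC lies at 3538 on the control array and at 9000 and 8279 on the DFO and 311 arrays, and CCNB1 is lower on both chelator arrays than on the control array.

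The second comparison asked the same question of 311. The hypoxia targets were again the group with the most members past the rule: 33 of 37 were higher, 0 lower and 4 within 2-fold, with a median of 2.17 (percentile 100). ADM was 20.9-fold higher, PFKFB4, an enzyme that sets the level of a glycolytic regulator, 18.4-fold, IGFBP3 15.7-fold and NDRG1 7.98-fold. TFRC was 2.34-fold higher, at 8279 on the 311 array. Mitosis genes were lower in 12 of 40 cases and higher in 0, with a median of -0.62 (percentile 0.0), including NDC80 at 3.88-fold lower, ASPM, a spindle pole gene, at 3.82-fold lower and the kinesin KIF11 at 3.50-fold lower.

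Glycolysis genes were higher in 15 of 20 measured cases and lower in 0 (median 1.27, percentile 100), with ENO2 at 15.5-fold and the hexokinase HK2 at 4.21-fold. VEGFA had a log2 ratio of -0.19 on its brightest probe set, whereas its other measured probe sets were past 2-fold, at 1.65, 1.37 and 1.21. Dioxygenases had a median of 0.20, within the random range (percentile 89.44, range 0.08 to 0.26), with 6 of 34 higher and 3 lower; 5 of the 6 higher members also stand on the hypoxia list. Iron handling genes split, with 4 of 22 higher and 3 lower (median 0.52, percentile 96.14, range 0.23 to 0.63). TFR2, a sensor of transferrin-bound iron, was 3.64-fold higher and STEAP3 3.50-fold, while FBXL5, the iron-sensing subunit that targets iron regulatory proteins for degradation, was 2.51-fold lower. Heme and iron-sulfur genes had a median of -0.06 (percentile 30.73, range -0.36 to -0.01), with 2 of 29 higher and 5 lower, among them HSCB at 3.20-fold lower. Metallothionein and zinc transport genes had a median of 2.98 (percentile 100; 0.19 without the _x_at and _s_at probe sets), with 7 of 12 higher and 1 lower, and MT1X was 22.8-fold and MT2A 16.2-fold higher.

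Of p53 targets, 13 of 30 were higher and 1 lower (median 0.48, percentile 99.76, range 0.30 to 0.71). GADD45A was 11.6-fold higher, CDKN1A 4.42-fold, the stress cytokine gene GDF15 3.17-fold and SESN1 3.13-fold. The G1/S and replication genes had a median of -0.22 (percentile 6.56, range -0.22 to -0.14), with 5 of 42 lower and 0 higher, and BRCA1 was 3.32-fold lower on its brightest probe set, with its other measured one at a log2 ratio of -0.27. CCND1 was within 2-fold at a log2 ratio of -0.32. Immediate early genes had a median of 1.84 (percentile 100), with 14 of 19 higher and 0 lower, such as FOS at 11.5-fold and FOSL1 at 8.06-fold. The ATF4 response had a median of 0.57, with 10 of 30 higher and 0 lower (percentile 99.93). ATF3 was 38.9-fold and PPP1R15A 16.6-fold higher. NF-kB targets had a median of 0.91, with 6 of 13 higher and 1 lower (percentile 99.88), including TNFAIP3 at 17.9-fold and NFKBIA, an inhibitor of NF-kB, at 3.46-fold. Unfolded protein response genes had a median of 0.43 (percentile 98.12, range 0.28 to 0.48), and 3 of 19 were higher and 0 lower, the chaperone DNAJB9 at 2.98-fold, HERPUD1 at 2.21-fold and MANF at 2.02-fold; after DFO the same list had a median of 0.08 (percentile 66.06, range 0.0071 to 0.24).

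Estrogen receptor targets and luminal genes were lower in 8 of 31 cases and higher in 1, with a median of -0.11 (percentile 5.62, range -0.30 to -0.01). The corepressor NRIP1 was 3.29-fold lower, GREB1 3.24-fold lower and the prolactin receptor PRLR 3.04-fold lower. Basal epithelial markers had a median of 2.15 over 5 measured genes (percentile 100), and of 1.25 without the _x_at and _s_at probe sets. By the rule 3 were higher, TRIM29 at 10.1-fold, EGFR at 4.69-fold and ITGB4 at 4.43-fold. The other 2 lay within 2-fold, CDH3 among them at a log2 ratio of -0.08. Of fibroblast and mesenchymal markers, 7 of 14 lay under the floor on both arrays, and the measured ones had a median of 1.00 (percentile 97.34, range 0.59 to 1.05), with ACTA2 3.04-fold and FN1 2.29-fold higher; after DFO the list had a median of 0.74 (percentile 93.39, range 0.42 to 0.83). Leukocyte markers were within 2-fold in all 6 measured cases, with a median of 0.86 (percentile 90.55, range 0.34 to 0.99), and in all 4 after DFO, with a median of 0.33 (percentile 47.57, range -0.03 to 0.48). Of the 12 leukocyte markers named on the array, 6 lay under the floor on both arrays for 311 and 8 for DFO. Only 2 were above the floor on the control array, so these 2 medians rest mainly on ratios with 1 side set to the floor.

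Across the array, 1910 of 13873 measured genes were higher and 1060 lower on the 311 array, of which 689 and 158 had a lower bound only. The lowest ratios included the semaphorin SEMA4C, 15.7-fold lower, and the insulin receptor substrate IRS1, 8.18-fold lower. ANKRD37, a hypoxia target, was at least 33.9-fold higher. The poly-A spikes were 9.002-fold and the 18S RNA 3.86-fold higher on the control array than on the 311 array by the same measure. The split again depended on the scaling: 64.3% of genes past the rule were higher as deposited, and 45.6% after loess centring, with 1116 higher and 1331 lower. It depended on the floor too, with 55.4% higher at the 60th percentile and 68.4% without a floor. As for DFO, the control floor of 36.97 lay under that of the 311 array, 47.45, which eased calls of higher genes among those with a lower bound. The median of all genes was 0.20 and loess centring moved it by -0.18. Relative to the median of all genes, the hypoxia list stood at 1.97 and the mitosis list at -0.82. Simulated arrays with no differences and 1 common floor gave 296.0 higher and 340.6 lower genes.

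The chelators had many genes past the rule in common. Among 12884 genes measured in both comparisons, 1518 were higher with DFO and 1658 with 311, and 879 of these were higher with both. This set leaves out genes under the floor on the control array and on 1 chelator array, which could be higher with 1 chelator only. With them, 1669 genes were higher with DFO and 1910 with 311, so the restriction raises the shared part of the higher genes. Independent lists of these sizes would share 195.3 genes, and simulated unchanged arrays with a common control shared 70.3. The simulated lists were smaller, with 196.5 genes higher for DFO and 296.0 for 311, so their overlap does not stand for lists of the observed sizes. Of 1209 genes lower with DFO and 1060 lower with 311, 603 were lower with both, against 99.5 for independent lists and 109.1 in the simulation. The simulated lists of lower genes were again smaller, at 246.2 for DFO and 340.6 for 311. Noise of the shared control array moves both ratios the same way, which holds down opposite calls, and the simulation did not count these. By the rule 2 genes passed in opposite directions. On their brightest probe sets these 2, CACNG4 and HIRIP3, were lower with DFO and higher with 311, whereas another measured probe set of each lay above the control array with both: at log2 ratios of 0.35 and 1.01 for CACNG4 and of 0.21 and 0.60 for HIRIP3. The remaining probe set of CACNG4 had signals of 169.0 on the control array, 34.3, under the floor, on the DFO array and 192.8 on the 311 array.

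Across the 10321 genes above the floor on all 3 arrays, the log2 ratios of the chelators correlated at r = 0.803 (Spearman's rho 0.791), where unchanged arrays with a shared control gave 0.698. Genes are not independent replicates. The covariance was 0.549 against 0.160 in the simulation, a difference of 0.389. When the DFO ratio of 1 probe set was set against the 311 ratio of another probe set of the same gene, over 4436 genes, the covariance was 0.357, against 0.544 with the same probe set. With 1 control array the controls could not be split, so part of the excess in overlap and correlation may come from the shared control.

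**Figure D3:**
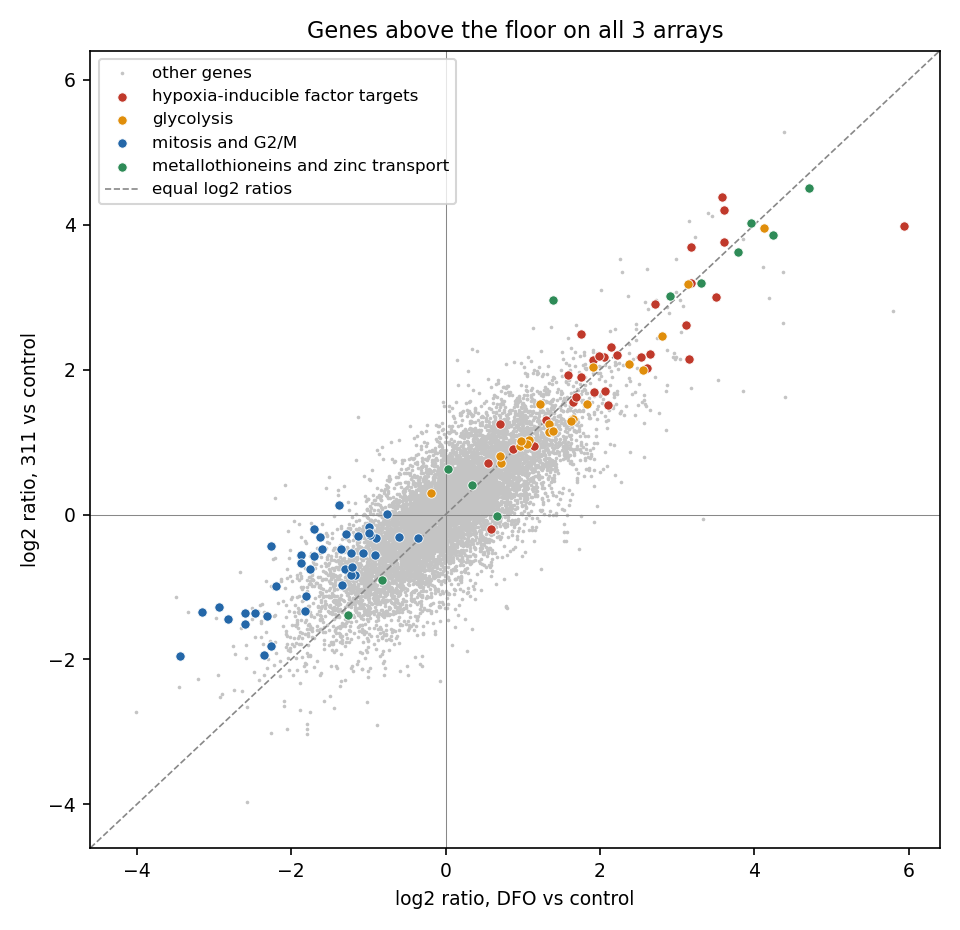
Log2 ratio of DFO against control (horizontal) and of 311 against control (vertical) for the 10321 genes above the floor on all 3 arrays, with 1 point per gene; coloured points are members of 4 gene lists and the dashed line marks equal ratios. Mitosis genes lie above the dashed line, with medians of -1.62 for DFO and -0.62 for 311, and the hypoxia list has medians of 2.10 and 2.17.

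The third comparison set the chelators side by side, without the control array; their concentrations differed 10-fold, so the values compare 250 µM of one with 25 µM of the other. Mitosis genes were higher on the 311 array than on the DFO array: 17 of 40 were higher by the rule, 0 were lower and all 40 ratios lay above 0, with a median of 0.86 (percentile 100). CDC20, an activator of the anaphase-promoting complex, was 3.56-fold higher with 311, HMMR 3.52-fold, CCNB1 3.15-fold and the securin PTTG1 2.85-fold. The G1/S and replication genes had a median of 0.31 (percentile 99.88), with 1 of 42 higher and 0 lower, POLE2 at 2.11-fold. The hypoxia targets had a median of 0.01 (percentile 35.71, range -0.0038 to 0.08), with 0 of 37 higher and 3 lower, and glycolysis genes had a median of -0.09 (percentile 7.36, range -0.30 to -0.09), with all 21 within 2-fold. IGFBP3 was 3.91-fold lower and LOX 3.70-fold lower with 311, while ADM was 1.75-fold higher.

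Iron handling genes had a median of -0.16 (percentile 4.17, range -0.24 to -0.12), with 1 of 21 higher and 2 lower. TFRC differed by a log2 ratio of -0.12 on its brightest probe set, within the SD of 0.198 found for probe sets of that brightness. Its 3 measured probe sets ran from -0.12 to 0.39. ID1 and SMAD7, targets of bone morphogenetic protein signalling that stand on the iron list, were 4.13-fold and 2.85-fold lower with 311, and TFR2 was 2.48-fold higher on its brightest probe set but had a log2 ratio of 0.0026 on its other measured one. Heme and iron-sulfur genes had a median of 0.20 (percentile 93.28, range -0.0004 to 0.23), with 0 of 29 higher and 1 lower. Oxidative phosphorylation genes had a median of 0.21 (percentile 99.30), all 31 within 2-fold, after medians of -0.18 with DFO (percentile 2.62, range -0.20 to -0.07) and 0.10 with 311 (percentile 43.70, range -0.03 to 0.23) against control. Unfolded protein response genes had a median of 0.27 (percentile 98.65), and NRF2 targets of 0.29 (percentile 98.82, range 0.14 to 0.36), with 1 of 20 higher. The zinc exporter SLC30A1 was 2.97-fold higher with 311, in a metallothionein and zinc list with a median of -0.10 (percentile 18.71, range -0.11 to 0.07).

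Medians of the p53 list (0.02, percentile 40.95, range -0.0083 to 0.08), the ATF4 list (0.01, percentile 35.76, range -0.02 to 0.04), the immediate early list (0.12, percentile 76.76), the NF-kB list (0.23, percentile 83.70, range 0.08 to 0.42), the dioxygenases (-0.04, percentile 20.33, range -0.13 to -0.0098) and the estrogen receptor list (0.10, percentile 74.42, range 0.05 to 0.10) lay within the random range. Single members differed more: CDKN1A had a log2 ratio of -0.90, and GADD45A was 2.42-fold and NFKBIA 3.09-fold higher with 311. ESR1 was 2.11-fold higher on its brightest probe set, and its 3 measured probe sets had log2 ratios of 0.08 to 1.25; of those above the floor on 1 of these arrays, 2 were lower and 2 higher with 311. Basal markers had a median of -0.73 over 5 genes (percentile 0.14, range -0.77 to -0.43), with 4 ratios below 0 and 1 above. By the rule 1 was lower with 311, TRIM29 at 2.04-fold, and 4 lay within 2-fold. Fibroblast markers had a median of 0.31 (percentile 81.35, range 0.21 to 0.47) and leukocyte markers of 0.56 (percentile 94.59, range 0.13 to 0.63).

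By the 2-fold rule 618 of 14101 measured genes were higher and 458 lower on the 311 array than on the DFO array, of which 257 and 140 had a lower bound only. The widest gaps included IGFBP5, which binds insulin-like growth factors, 10.5-fold lower with 311, NPTX1 7.95-fold lower and GJB2 6.78-fold lower, and, in the other direction, the calcium channel subunit CACNG4 at 5.58-fold, the matrix gene EFEMP1 at 5.56-fold, the helicase RECQL4 at 5.40-fold and ODC1 at 5.12-fold higher. These are values of the brightest probe sets. The 3 measured probe sets of IGFBP5 had log2 ratios of -3.40 to -0.56. The 2 of CACNG4 were at 0.66 and 2.48 and the 2 of RECQL4 at 1.01 and 2.43. The brightest of RECQL4 had a signal of 45.7 on the DFO array, close to the floor of 45.11. As deposited, 57.4% of the genes past the rule were higher. After loess centring 457 were higher and 576 lower, or 44.2%. With the floor at the 60th percentile, 51.2% were higher. Simulated arrays with no differences and 1 common floor gave 100.4 higher and 93.7 lower genes.

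**Figure D4:**
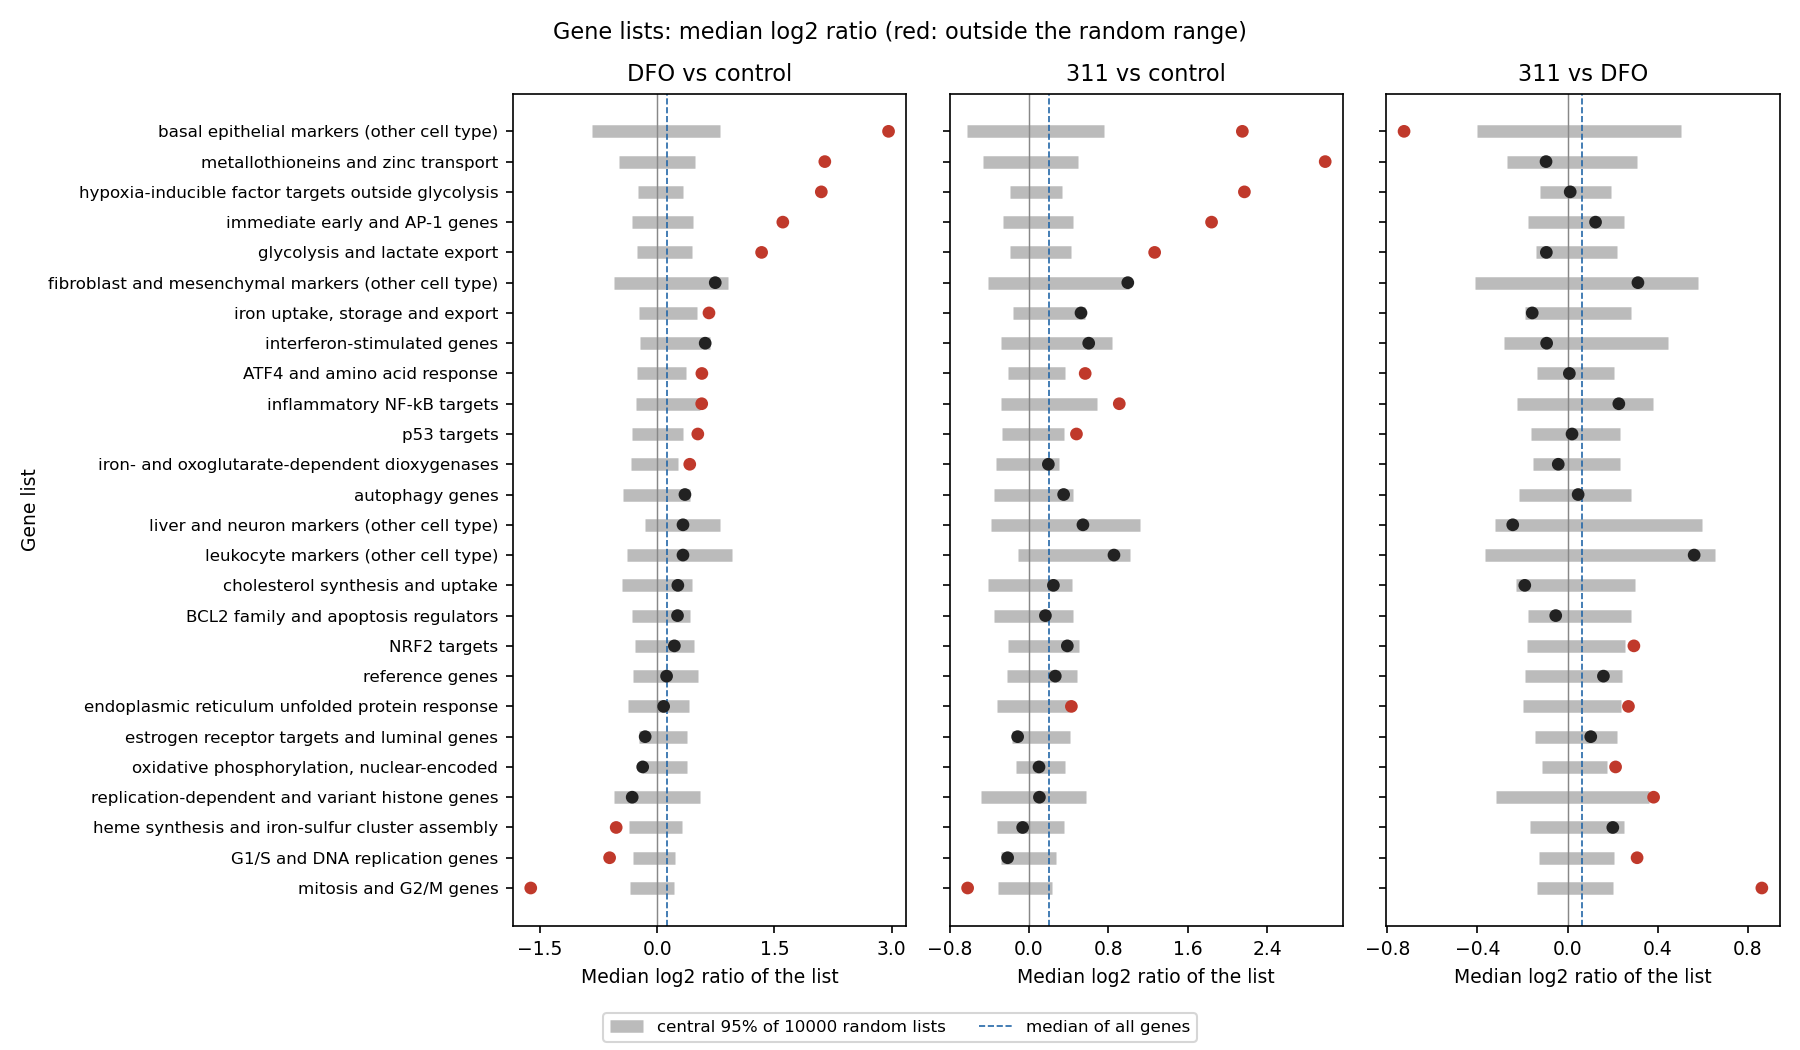
Median log2 ratio of each of the 26 gene lists in the 3 comparisons (horizontal axes, which differ in scale between panels), with grey bars for the central 95% of 10000 signal-matched random lists, red points for medians outside it, and a dashed line at the median of all genes. Outside the range lie 13 lists for DFO, 10 for 311 and 7 for 311 against DFO, 30 of 78 in all, where 3.9 would be expected by chance from independent lists. The 3 comparisons share arrays and some lists share genes, so the 78 medians are not independent and the 3.9 makes no test.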

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

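Of the tests in this part, those of array preparation, of culture differences, of unequal doses and of the basal markers were chosen after the results were seen; those of scaling and of the floor were chosen before.

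The hypoxia and glycolysis lists were higher on both chelator arrays than on the control array, whose poly-A spikes and 18S RNA also stood apart. A preparation difference that acts alike on genes of equal signal should leave these lists, fixed before their values were seen, among random lists of equal signal, but the lowest of their 4 percentiles was 100. Scaling does not account for the pattern either, since the lowest hypoxia median over 3 scalings and both comparisons was 2.0293. What stays open is a preparation step that acts on particular transcripts, and differences between cultures other than the chelators, which cannot be told apart from the treatment with 1 array per condition. The biological explanation that the design names, a response to iron chelation shared by both compounds, remains an untested hypothesis.

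The mitosis list was lower on the DFO array than on the 311 array, in a comparison that does not use the control array. Neither scaling nor the floor accounts for it, because its median log2 ratio of 311 to DFO was at least 0.8407 over 3 scalings and 3 floors. The concentrations differed 10-fold with 1 concentration per compound, so a difference between the compounds cannot be told apart from a difference in effective dose, nor, with 1 array per condition, from other differences between the cultures. The TFRC and hypoxia values, which were close on both arrays, do not show that the effective doses were equal.

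TRIM29, EGFR and ITGB4, fixed as markers of basal epithelium, were higher on both chelator arrays. CDH3, another marker on that list, lay within 2-fold on both, at log2 ratios of 0.47 with DFO and -0.08 with 311. Basal cells mixed into the treated cultures would bring their abundant keratins, but KRT5 reached at most 14.9 on the chelator arrays, under both floors, while KRT14 was above the floor on the 311 array only, at 62.9. A single faulty probe set is also argued against, as each of the 3 genes had at least 2 probe sets that were higher by 2-fold on both arrays. Of the 10 markers listed, 6 were named on the array, and 4 of these were above the floor on the control array. The floor is not a detection call, so this does not show that the line itself expresses them. What stays open, as for the hypoxia list, is a preparation step that acts on particular transcripts, culture differences other than the chelators, and an untested response of the MCF-7 cells to chelation; with 1 array per condition these cannot be told apart.

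Control probe sets outside the comparisons carried a signal above the chelator arrays: by the median of the probe sets' ratios, the poly-A spikes on the control array were 7.769-fold above the DFO array and 9.002-fold above the 311 array. The 18S RNA was 5.0-fold above the DFO array and 3.862-fold above the 311 array.

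For 10 named genes, the DFO and 311 arrays lay on opposite sides of the control array on the brightest probe set, each by more than the SD of a probe set's log2 ratio over all signals; none of these differences was tested. The log2 ratio of 311 to DFO was 1.9122 for ANKRD10, 2.4806 for CACNG4, at least 1.9653 for COL1A1, at least 2.6749 for HIRIP3 and at least 2.3814 for SLC27A4, all lower with DFO and higher with 311. It was -1.1944 for the apoptosome gene APAF1 (up to 0.24 on its other probe sets, which were higher with both chelators than in control), -2.0496 for EPPK1, -2.0473 for ID1, -1.254 for the amino acid transporter SLC38A2 and -2.0829 for ZNF791, all higher with DFO and lower with 311 on that probe set. Of their other probe sets above the floor on all arrays, 1 each of CACNG4, HIRIP3, EPPK1 and SLC38A2 was higher with both chelators and that of ANKRD10 lower with both, whereas 1 each of EPPK1, SLC38A2 and ZNF791 lay on the same sides as the brightest, as did 1 of CACNG4 that was under the floor with DFO. The DFO value of APAF1, 0.50, lay under the SD of 0.58 at its brightness.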

How the results depend on the processing

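All alternatives were chosen before the data were examined. A value with no replicates was called moved when it differed by more than the SD of a probe set's log2 ratio, a correlation by more than its simulated SD, and a count by more than 1.5 times. Of the list medians under the alternatives, 613 stayed within this spread, 10 moved and 1, among lists outside the random range, reversed; over all lists, 17 of 78 medians turned sign under at least 1 alternative, 16 of them within the random range, and 41 more moved by over 1.5 times, with ranges beside the values; of the named genes' values, 2644 stayed, 160 moved and 3 reversed; of the counts, 49 stayed and 31 moved. Signal over background limits the counts, because genes under the floor have no order. The cause was not tested for any of the following values unless stated.

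Without a floor, which admits the dimmest signals by construction, 4578 genes were higher and 2523 lower for DFO against 1669 and 1209, 4921 and 2271 for 311 against 1910 and 1060, and 2635 and 2175 for 311 against DFO in place of 618 and 458, with 2935 higher and 1028 lower under both chelators against 879 and 603. With the 40th percentile, 311 against DFO gave 1117 higher and 771 lower genes, and with the 60th percentile 316 and 301, while 1162 were higher for 311 and 585 under both. A 1.5-fold rule, which is wider by construction, gave 3623 higher and 2589 lower for DFO, 4221 and 2402 for 311, 2172 and 1588 for 311 against DFO, and 2265 and 1641 under both. A 3-fold rule gave 466 and 331, 464 and 292, 73 and 72, and 220 and 128 in the same order. Loess centring gave 1116 higher genes for 311.

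The correlation between the chelators' ratios, 0.8033, was 0.7803 with quantile scaling, 0.7678 with loess, 0.785 and 0.8165 with the 40th and 60th percentile floors, 0.6397 without a floor and 0.7977 without _x_at and _s_at probe sets. The covariance of 0.5437 was 0.3571 across different probe sets of a gene.

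Without _x_at and _s_at probe sets, the metallothionein and zinc list was at 0.184 for DFO and 0.1931 for 311, because all its metallothionein values come from such probe sets; it was at 2.3835 for 311 with the mean of probe sets. The same change reversed the dioxygenases for DFO to -0.02 and took the basal markers to 2.4487 for DFO and 1.2456 for 311. Without a floor, the basal markers were at 1.7113 and the NF-kB targets at 1.1038 for DFO, which loess centring put at 0.2677. For 311 against DFO, the leukocyte markers were at 0.1253 with the 60th percentile floor, and the liver and neuron markers at 0.2627 with the 40th percentile and 0.3418 without a floor, against -0.2434. Single genes reversed in 3 cases: MCL1 for DFO from 1.33 to -0.9929 and HNMT for 311 from -2.89 to 0.7881 without _x_at and _s_at probe sets, and POLH for 311 against DFO from -1.02 to 0.1331 with the mean of its probe sets.

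No paired analysis was possible because each condition had 1 array and no test was made.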

Other observations

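Autophagy genes were higher in 5 of 18 measured cases with DFO (median log2 ratio 0.36, percentile 95.57, range 0.23 to 0.42) and in 5 of 19 with 311 (0.35, percentile 93.77, range 0.15 to 0.46), and 0 were lower. The light chain gene MAP1LC3B was 3.55-fold and 3.21-fold higher, and the kinase gene ULK1, which starts autophagy, was 4.02-fold higher with DFO and 2.67-fold lower with 311 than with DFO; the list's median between the chelators was 0.05 (percentile 52.09, range -0.05 to 0.07). Among regulators of apoptosis, BCL2A1, an inhibitor of apoptosis and a target of NF-kB, was 7.90-fold higher with DFO and 8.43-fold with 311, and the initiator caspase CASP8 was 3.10-fold and 4.64-fold lower. That list's medians were 0.26 with DFO (percentile 85.12), 0.17 with 311 (percentile 69.86, range -0.14 to 0.21) and -0.05 between them (percentile 17.87, range -0.19 to -0.009), with 4 of 23 higher and 1 lower for DFO and 3 of 21 higher and 1 lower for 311. Of NRF2 targets, 3 of 20 were higher with DFO (median 0.22, percentile 73.71, range 0.16 to 0.38) and 2 of 20 with 311 (0.39, percentile 90.40, range 0.32 to 0.66). The glutathione synthesis enzyme GCLC was 4.54-fold and 3.19-fold higher.

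Interferon-stimulated genes were higher in 3 of 14 cases with DFO (median 0.61, percentile 95.26) and in 2 of 12 with 311 (0.60, percentile 85.09, range 0.19 to 0.66), and between the chelators their median was -0.09 (percentile 16.95, range -0.20 to 0.11). IRF1 was 2.39-fold and 3.83-fold higher on its brightest probe set, while its other probe set was lower than in control, with a log2 ratio of -0.50 with DFO and a signal of 9.5, under the floor, with 311. Cholesterol synthesis genes were higher in 4 of 17 cases with DFO (median 0.27, percentile 91.49, range 0.07 to 0.33) and in 1 of 17 with 311 (0.25, percentile 87.70, range -0.15 to 0.33), and had a median of -0.19 between them (percentile 5.15, range -0.30 to -0.19). Histone genes had medians of -0.32 with DFO (percentile 12.68, range -0.37 to 0.03), 0.11 with 311 (percentile 56.63, range -0.42 to 0.15) and 0.38 between the chelators (percentile 98.22, range 0.07 to 0.50). Reference genes had medians of 0.12 (percentile 52.24, range -0.03 to 0.19), 0.26 (percentile 76.98, range 0.06 to 0.31) and 0.16 (percentile 87.87, range -0.02 to 0.16), and liver and neuron markers of 0.33 (percentile 42.94, range 0.03 to 0.72), 0.54 (percentile 57.69, range 0.12 to 0.73) and -0.24 (percentile 5.19, range -0.35 to 0.34). Of the 12 liver and neuron markers named on the array, 4 were above the floor on the control array, so their medians against control rest partly on ratios with 1 side set to the floor. HIF1A and EPAS1, which encode the alpha subunits of hypoxia-inducible factors and were chosen after their values were seen, had log2 ratios of opposite sign: HIF1A was at -1.57 with DFO and -1.78 with 311, and EPAS1 at 1.68 and 1.24.

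Genes whose symbols begin with ZNF and a number, which mostly encode zinc finger proteins, were lower on the chelator arrays than on the control array, a pattern noticed in the data; the tests were chosen before their own results were seen, except that of culture differences. With DFO their median was -0.17 over 396 genes, where random lists of equal signal gave 0.11 to 0.29, and with 311 it was -0.32 over 389 genes, where random lists gave 0.19 to 0.39. By the 2-fold rule 12.4% were lower with DFO and 23.9% with 311, against 8.83% and 7.64% of all measured genes. Low signal does not account for this, since the higher of the percentiles among signal-matched lists was 0.0. The control array's preparation cannot account for the part between the chelators, where the median of 311 to DFO was -0.17 over 372 genes (percentile 0.0), and its share in the part against the control stays open. Also open are culture differences other than the chelators, which cannot be told apart from an effect of chelation with 1 array per condition.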
